A study of Mus musculus with 35 samples.

How the data were processed

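RNA was sequenced from sorted bone marrow cells of transplanted mice that carried 1 of 3 leukemia fusion genes under doxycycline control (NUP98-DDX10, NUP98-JARID1A or NUP98-NSD1). Per the labels' protocols, cells were sorted for GFP and CD45.2, total RNA was extracted, and stranded poly-A libraries were made by a facility. Treated mice got doxycycline at 4 mg/ml for 3 or 5 days. The 33 RNA libraries formed 10 groups. Each fusion had 4 untreated libraries (1 titled day 3 and 3 titled day 5, pooled as 1 group), 3 doxycycline libraries of day 3 and 3 of day 5. The remaining 3 libraries are titled as controls. Their labels list all 3 fusions and no treatment, so what they carry is not known from the labels. The series holds 35 samples; the 2 chromatin immunoprecipitation samples (HA-tagged fusion and input) were not analysed here. The labels number libraries within a group but do not number animals or primary leukemias, so the p-values measure only the spread between these samples.

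The authors named STAR, SAMtools, featureCounts and DESeq2, per the submitters' processing notes, which give no versions and the builds GRCm38 and mm10. Whether strand was used in counting is not stated. The deposited table holds 24462 features, of which 24454 are genes by Entrez identifier and 8 are named for constructs (fusion genes, eGFP and luciferase). The unit of the deposited values is signal, here normalized counts, that is reads divided by 1 size factor per library. In every library 100% of the values were whole multiples of 1 step, within a tolerance of 0.01 reads and with a largest deviation of 3.8e-09. The reads recovered this way summed to 12043487 to 17513924 reads per library in the controls, 12510513 to 15554633 in NUP98-DDX10, 14839207 to 28903870 in NUP98-JARID1A and 14752618 to 17911797 in NUP98-NSD1. No 2 libraries held the same reads: the chi-square per degree of freedom between libraries of 1 group ran from 6.91 to 385. Symbols and positions came from the GRCm38 annotation, which matched 24376 genes; 78 stayed without a symbol.

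The main model was limma 3.58.1 in R 4.3.3 on log2(value + 1) of the authors' normalized counts, 1 fit of 10 group means over all 33 libraries with a mean-variance trend (27.3 degrees of freedom in total). Features with a value of at least 10 in at least 3 libraries were kept, 12682 genes and 5 constructs. Benjamini-Hochberg adjusted p under 0.05 was the threshold; a gene past it is said to rise, fall or change. All log2 fold changes are on this scale, which understates the change of genes with few reads, and a value after ± beside one is its standard error. The comparisons were each fusion's day 3 and day 5 libraries against its untreated ones, the mean of the 3 fusions at each day, day 5 against day 3, the untreated fusions against the controls, and F-tests of differences between the fusions in the effect of doxycycline and in the untreated state. Floors for a count of 0 (3 reads) cover counting error only, and reads without molecular identifiers are not independent molecules. A value after ± beside a group mean of normalized counts is the SD over its libraries, and not every mean is printed with one.

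Before the data were examined, the groups, the tests, the threshold, 23 gene lists, the rule for named genes and the alternatives were fixed. Named genes were Cdk6 and the genes of the fusion parts, and in each mean comparison the 10 largest rises and 10 largest falls past the threshold. These had to have the same sign in all 3 fusions, a mean above the median of the genes kept (387.1) and a plain gene symbol. The up to 4 members of each list with the smallest adjusted p, the 10 genes with the smallest p of each F-test and the 3 largest rises and falls per fusion and day completed the rule. A few genes under this rule are not reported here. Other list members are named as examples of a count and were chosen after their values were seen. Lists were tested with limma's camera against all other genes, with a preset correlation of 0.01 between genes and again with an estimated one, adjusted over the 22 lists of a comparison. Counts of list members are given over all genes tested and adjusted over the list alone, and where 1 count is given both were equal.

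The lists, with the members matched, were the fusion part genes (4), G1 cyclins, kinases and inhibitors (18), Hoxa and Hoxb genes with Meis1 and Pbx3 (21), progenitor and leukemia stem cell genes (30), primary granule genes (10), secondary and tertiary granule and mature neutrophil genes (35), monocyte and macrophage genes (27), dendritic cell genes (12) and MHC class II genes (9). Further lists held mitosis genes (31), DNA replication genes (38), MYC target and ribosome biogenesis genes (30), p53 target and apoptosis genes (22), interferon response genes (32), ATF4 stress response genes (23) and immediate early and heat shock genes (22). The lists of other cell types were erythroid (17 of 18), B cell (14 of 17), T and NK cell (16 of 19), basophil, mast cell and eosinophil (16), megakaryocyte (12) and endothelial and stromal genes (13). None of the 13 mitochondrially encoded genes had a feature in the table (0 of 13), so that list was not used here. Several genes are in more than 1 list, among them Cdkn1a, Sesn2 and Flt3.

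Whether the replicate numbers in the titles pair libraries across groups was decided before calls were compared, from correlations of the libraries' deviations from their group means. Of 27 pairs with the same number 6 correlated above 0.1 (range -0.627 to 0.628), and the best match had the same number in 6 of 27. The numbers were therefore not used as pairs in the main model. Between the doxycycline and untreated day 5 groups, however, the same-number correlations were 0.628, 0.345 and 0.211 in NUP98-JARID1A. They were 0.166, 0.073 and 0.372 in NUP98-NSD1 and -0.095, -0.422 and -0.237 in NUP98-DDX10. Pairing within day 5 of the first 2 fusions is thus not excluded. On simulated reads, the model recovered 46.3% of genes changed 1.5-fold in NUP98-DDX10 at day 5, 97% of those changed 2-fold and 98.5% of those changed 4-fold, with 14 false calls among 12583 genes. For the mean of the fusions at day 5 these were 97%, 100% and 100% with 11 false calls. With no simulated change, NUP98-DDX10 at day 3 and the F-test at day 5 gave 0 calls. The simulation gave every library the same dispersion of 0.02 and changed only genes above a set mean level. The real libraries differed in spread within groups (chi-square per degree of freedom 6.91 to 385). These rates therefore check the model and do not give its recovery or false calls on the real data.

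Alternatives changed 1 choice at a time. They were pseudocounts of 0.1 and 5, no filter, a limit 10 times higher, TMM factors (edgeR 4.0.16), quantile normalization, edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, a fit of the compared groups only, a replicate block, limma's sample weights, untreated libraries titled day 5 only, and leaving out each library in turn. Added after the data were seen were the mean without NUP98-JARID1A, a replicate block over its day 5 libraries alone, and all libraries drawn down to equal depth. A result with a test kept its verdict when direction and side of the threshold were unchanged, and a count when it stayed within 1.5 times the main count.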

Results

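Gene expression was measured in 33 RNA libraries, all but 3 of them from mouse leukemia cells that carried a doxycycline-repressed NUP98 fusion gene. NUP98-DDX10, NUP98-JARID1A and NUP98-NSD1 join the start of the nucleoporin gene NUP98 to parts of an RNA helicase gene (DDX10) or of chromatin regulator genes (KDM5A, also named JARID1A, and NSD1). The mouse counterparts of these genes are Nup98, Ddx10, Kdm5a and Nsd1. Each fusion had 4 untreated libraries, 3 after 3 days of doxycycline and 3 after 5 days, and 3 libraries are titled as controls. The reads in genes ran from 12043487 to 28903870 per library. The series title names Cdk6 as a direct transcriptional target of the fusions, and the doxycycline groups measure which transcripts change after the fusion is switched off.

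The fusion transcripts fell in all 3 models. The NUP98-DDX10 transcript went from 12450 ± 2381 normalized counts (SD, n = 4) to 4.98 ± 2.10 at day 3 (n = 3) and 6.30 ± 1.87 at day 5, and 0.040% and 0.0506% of the untreated mean was left. The NUP98-NSD1 transcript fell from 54850 ± 2575 to 49.1 ± 2.53 and 46.5 ± 10.1, with 0.0896% and 0.0847% left. The NUP98-JARID1A transcript fell from 3225 ± 202 to 96.4 ± 5.55 and 85.3 ± 21.9, with 2.99% and 2.65% left. In log2 terms the changes were -11.06 ± 0.29 and -10.75 for NUP98-DDX10 (adjusted p = 3.6e-21 and 7.73e-21), -10.10 ± 0.26 and -10.19 for NUP98-NSD1 (2.6e-21 and 2e-21) and -5.05 ± 0.49 and -5.26 for NUP98-JARID1A (4.86e-08 and 2.09e-09). The eGFP transcript fell with the fusion in each model, and 0.0336%, 0.11% and 2.90% of it was left at day 3 for NUP98-DDX10, NUP98-NSD1 and NUP98-JARID1A, although cells had been sorted for GFP per the protocol. Luciferase was not past the test in any fusion at either day, with a standard error of 0.68 from a spread that includes the controls (473, 9 and 9). In NUP98-JARID1A each doxycycline library (4708 to 6072) lay above each untreated one (2627 to 4149). The same held for NUP98-DDX10 at day 5 (1904 to 2688 against 1242 to 1774) but not at day 3. In NUP98-NSD1 the day 3 libraries lay below the untreated ones (1615 to 1832 against 1844 to 2245), and those of day 5 overlapped them. The controls held 2, 63 and 14 reads of NUP98-JARID1A, up to 72.0 normalized counts, and no reads of the other fusions. Of the mouse counterparts of the fusion parts, which are features apart from the constructs, 0 of 4 passed limma's test at day 3 in the mean of the fusions, with 0 at an unadjusted p under 0.05 and 0 by edgeR and by DESeq2 (camera adjusted p = 0.563). At day 5 Ddx10 fell by 0.22 (adjusted p = 0.0213), and Nup98 had -0.13 (0.0901). Without NUP98-JARID1A day 5 replicate 3 or NUP98-NSD1 day 5 replicate 2, Ddx10 had -0.17 (0.0675) and -0.19 (0.0542), and without the untreated day 3 library of NUP98-JARID1A, Nup98 had -0.16 (0.0315).

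**Figure D1:**
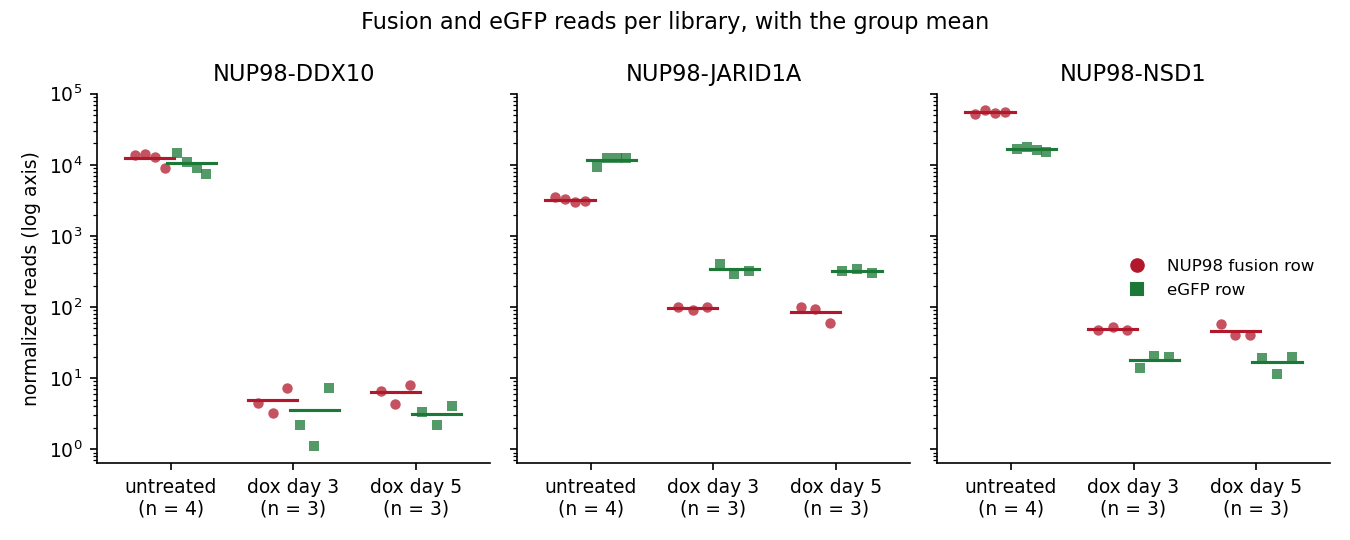
Normalized counts of each model's own fusion transcript (circles) and of eGFP (squares) on a log axis, 1 point per library, with a bar at the group mean, for untreated (n = 4), day 3 and day 5 doxycycline libraries (n = 3 each). The NUP98-JARID1A doxycycline libraries lie between 60.2 and 100.3 normalized counts of the fusion.

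Cdk6 (Entrez gene 12571, GRCm38 chromosome 5, 3341004 to 3531008), which encodes a kinase of the G1 phase of the cell cycle, fell after doxycycline. In NUP98-NSD1 it went from 20090 ± 1343 normalized counts untreated (SD, n = 4) to 10190 ± 595 at day 3 (n = 3) and 5365 ± 1751 at day 5. In NUP98-JARID1A it went from 16520 ± 325 to 9176 ± 1341 and 4062 ± 849, and in NUP98-DDX10 from 13920 ± 1313 to 12280 ± 580 and 7802 ± 772. At day 5 each of the 9 doxycycline libraries lay below each untreated library of its fusion. The controls had 2889 ± 1433 (n = 3). The mean change over the fusions was -0.67 ± 0.14 at day 3 (adjusted p = 0.000865) and -1.61 ± 0.14 at day 5 (2.16e-10), a 3.05-fold fall. At day 3 the change was past the test in NUP98-JARID1A (-0.86, adjusted p = 0.013) and NUP98-NSD1 (-0.98, 0.008) and not in NUP98-DDX10 (-0.18, 0.81), but the effects did not differ between the fusions by the F-test (adjusted p = 0.237). At day 5 they did differ (adjusted p = 0.0119), with -0.83 in NUP98-DDX10, -2.04 in NUP98-JARID1A and -1.95 in NUP98-NSD1. The related kinase gene Cdk4 fell by 0.71 at day 5 (adjusted p = 2.15e-13), and the inhibitor genes Cdkn1a (0.88) and Cdkn2d (0.66) rose. Of the 18 genes of the G1 list, 5 rose and 2 fell at day 3 (6 and 2 adjusted over the list alone), and 6 rose and 5 fell at day 5. As a list they did not move at day 3 (camera adjusted p = 0.108) or day 5 (0.897, where median and mean differ in sign, 0.01 and -0.04).

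**Figure D2:**
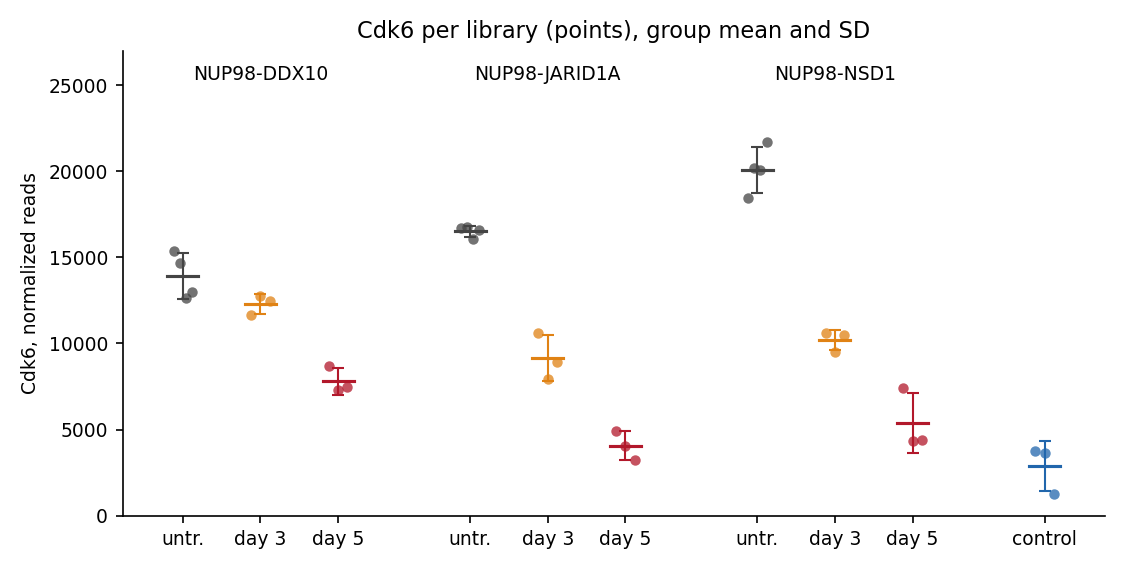
Normalized counts of Cdk6 per library (points) with the group mean and SD on a linear axis from 0, for the controls and for the untreated, day 3 and day 5 libraries of each fusion. Group means fell from untreated to day 5 in each fusion, to 7802, 4062 and 5365 for NUP98-DDX10, NUP98-JARID1A and NUP98-NSD1.

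After 3 days of doxycycline, Hox and progenitor genes were lower in the mean of the fusions. The homeobox gene Hoxa10 (GRCm38 chromosome 6, 52231197 to 52240854) fell by 1.22 (SE 0.11, adjusted p = 1.34e-08), its partner gene Meis1 (chromosome 11, 18880428 to 19019651) by 1.89 (SE 0.26, 6.02e-06), and Hoxa7 by 1.20 (2.19e-07). Sox4, a transcription factor gene of progenitors, fell by 2.74 (SE 0.26, 2.11e-08) and Angpt1, which encodes a ligand of the Tie2 receptor, by 2.38 (5.03e-06). The mucin gene Muc13 had the largest fall of the named genes, -3.14 ± 0.34 (2.62e-07). Further large falls were those of the adhesion receptor gene Adgrg1 (-1.81 ± 0.18, 3.45e-08), Bahcc1 (-1.80 ± 0.21), Tsc22d1 (-1.56 ± 0.13), the costimulatory receptor gene Cd28 (-1.52 ± 0.22), Heg1 (-1.50) and Tns1 (-1.48). The proteoglycan gene Vcan rose by 2.04 ± 0.35 (0.00015), the myeloid receptor gene Tarm1 by 1.86 ± 0.29 (3.59e-05), Fn1 for fibronectin by 1.53 ± 0.41 (0.00939) and Tgfbi, a secreted matrix protein gene, by 1.47 ± 0.12 (9.15e-10). Cd302 (1.42), S100a6 (1.23), Lpcat4 (1.22), Klf4 (1.18) and Fpr2 (1.18) were among the other large rises.

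Of the 17 tested genes of the Hox list, 10 fell and 1 rose (11 and 1 adjusted over the list alone), and the median was -1.20 (camera adjusted p = 1.13e-08, and 0.0117 with an estimated correlation). Of 27 progenitor genes 17 fell (19 adjusted over the list alone), among them Sox4, Angpt1 and Kit (-0.97), with a median of -0.53 (1.37e-09, and 0.0117 with an estimated correlation). Of 27 monocyte and macrophage genes 11 rose (13 over the list alone), such as Apoe (1.14) and Lgals3 (0.87), and the camera adjusted p was 1.48e-07 (0.0674 with an estimated correlation). In NUP98-DDX10 alone 1 of 27 rose at day 3 (2 over the list alone, median -0.05 and mean 0.07, camera 0.351). Of 21 ATF4 stress response genes 16 rose (17 over the list alone), with Mthfd2 at 0.80 ± 0.07 (adjusted p = 1.6e-08), Trib3 at 1.53 (5.56e-05) and Asns at 0.93 (0.00192), and camera gave 1.62e-09 (0.0117 with an estimated correlation). Of 31 mitosis genes 19 rose (25 over the list alone), by small amounts such as 0.39 for Cdca8 and 0.47 for Cdk1 (2.9e-14, but 0.0989 with an estimated correlation). Of 31 interferon response genes 21 fell (23 over the list alone), with Irf7 at -0.96 (0.00061) and Ifih1 at -0.59 (0.000481), and the camera adjusted p was 4.3e-10 (0.319 with an estimated correlation). Secondary granule and mature neutrophil genes (2 of 35 rose, neither over the list alone, camera 0.0371, 0.776 with an estimated correlation) and T and NK cell genes (5 of 16 fell, 0.0108, 0.249 with an estimated correlation) had weaker calls.

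The other lists were not past camera at day 3. DNA replication genes had 5 of 38 higher, such as Cdc45 (0.35) and Rrm2 (0.28), and camera adjusted p = 0.205. MYC target and ribosome biogenesis genes had 0 of 30 past limma's test, also over the list alone, with 3 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2 (0.328). Of 10 primary granule genes 2 fell (0.0569), of 12 dendritic cell genes 4 fell, among them Itgax (-1.04) (0.168), and of 9 MHC class II genes 1 fell, H2-Ob at -1.12 (0.66). Of 21 p53 target and apoptosis genes 5 rose (5 higher and 2 lower over the list alone), among them Bax (0.33) and Zmat3 (0.49) (0.136). Immediate early and heat shock genes had 3 higher, with Nr4a1 at 0.91, and 2 lower of 22 (0.177). Erythroid genes (camera 0.264) and B cell genes (0.549) each had 0 of 13 past limma's test, with 1 at an unadjusted p under 0.05 and 0 by edgeR and by DESeq2. Basophil genes (4 of 15 lower, 0.129), megakaryocyte genes (1 of 9 lower, 0.37) and endothelial genes (1 of 7 lower, 0.775, median 0.09 and mean -0.22) completed the lists. Some of these counts rested on calls that were lost when 1 library was left out. Ctsg (-0.60, adjusted p = 0.0385) lost its call in 18 of 21 such fits (0.0504 to 0.0739), the dendritic cell genes Siglech in 18 (0.0506 to 0.0961) and Cd300c in 15 (0.0537 to 0.121), Dusp2 in 17 (0.0517 to 0.0989), and the basophil genes Ms4a2 in 15 (0.0508 to 0.113) and Mcpt8 in 12 (0.0503 to 0.0709). Lyz2 of the neutrophil list lost its call in 9 (0.0526 to 0.0745) and Gp9, the megakaryocyte gene, in 6 (0.0525 to 0.0787). In all, 2353 of 12682 genes (18.6%) passed the test at day 3, 1100 higher and 1253 lower (1116 and 1111 after quantile normalization), and of these 97 rose and 237 fell at least 2-fold.

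At day 5 monocyte genes were higher and Hox and progenitor genes were lower in the mean of the fusions. Muc13 was -5.90 ± 0.34 against untreated (adjusted p = 1.79e-13), Sox4 -4.79 ± 0.26 (2.71e-14), Angpt1 -4.60 ± 0.32 (5.21e-12) and Meis1 -2.60 ± 0.26 (3.74e-09). Hoxa10 fell by 2.26 (SE 0.11, 4.54e-15), Hoxa9 (GRCm38 chromosome 6, 52223097 to 52227370) fell by 2.32 (SE 0.33, 1.88e-06) and Hoxa7 by 1.98 (1.81e-12). The receptor gene Kit, which marks progenitors, fell by 2.48 (SE 0.22, 4.49e-10) and Myc by 1.04 (SE 0.08, 2.85e-11). Cnn3 (-2.90 ± 0.23), Tns1 (-2.86 ± 0.20), Bahcc1 (-2.84 ± 0.21), Adgrg1 (-2.77 ± 0.18), Cd28 (-2.57 ± 0.22) and Chdh (-2.37 ± 0.20) were the other large falls. Among the rises, Vcan reached 3.73 ± 0.35 (1.65e-09), Fn1 3.42 ± 0.41 (1.19e-07) and Tarm1 3.09 ± 0.29 (1.16e-09). Fpr2, a formyl peptide receptor gene of neutrophils and monocytes, rose by 2.66 ± 0.33 (2.19e-07), Zfp36l1 by 2.63 ± 0.21, the complement gene C1qb by 2.62 ± 0.38, S100a6 by 2.61 ± 0.19 and Lifr by 2.55 ± 0.22.

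Of 27 monocyte and macrophage genes 24 rose and 1 fell at day 5, with Apoe at 2.36 ± 0.16 (adjusted p = 3.61e-12) and Fcgr1 at 2.49 (2.08e-10), and camera gave 3.66e-12 (0.0126 with an estimated correlation). The gene that fell was Ly6c2 (-0.33). Secondary granule and mature neutrophil genes had 30 of 35 higher, among them Lyz2 (1.21, adjusted p = 3.92e-07), Itgam (1.17) and Ltf (1.91), with camera at 3.4e-07 (0.621 with an estimated correlation). Primary granule genes had 9 of 10 lower, with Ctsg at -1.84 ± 0.20 (2.62e-08), Nkg7 at -1.78 and Cst7 at -1.22 (camera 5.7e-06, 0.165 with an estimated correlation). Of 27 progenitor genes 22 fell (1.16e-10, 0.0126 with an estimated correlation), and of 17 Hox list genes 13 fell and 1 rose (14 and 1 over the list alone, 6.14e-08, 0.0126 with an estimated correlation). Of 38 DNA replication genes 33 fell and 1 rose, with the helicase gene Mcm7 at -0.61 ± 0.05 (1.39e-10), Pole at -0.67, Dtl at -0.74 and E2f2 as the riser (0.83), and the camera adjusted p was 3.66e-12 (0.0549 with an estimated correlation). MYC target and ribosome biogenesis genes had 23 of 30 lower (24 over the list alone), with Apex1 at -0.76, Srm at -0.72 and Nop56 at -0.59 (6.82e-09, 0.114 with an estimated correlation). Of 21 p53 target and apoptosis genes 12 rose and 3 fell (13 and 3 over the list alone), among them the pro-apoptotic Bcl2l11 (0.72, adjusted p = 1.27e-09), Trp53inp1 (0.76) and Btg2 (0.76), with camera at 0.00155 (0.0549 with an estimated correlation). Immediate early and heat shock genes had 15 of 22 higher and 2 lower, with Ier5 at 1.77 ± 0.14, Junb at 1.22 and Dusp2 at -1.52 (0.000414, 0.284 with an estimated correlation). Of 31 interferon genes 11 fell (10 over the list alone), among them Usp18 (-1.24) and Oas1a (-0.79) (0.0126, 0.763 with an estimated correlation). By fusion 21 fell in NUP98-DDX10 (23 over the list alone, 9.46e-11, 0.444 with an estimated correlation). In NUP98-JARID1A 1 fell (0 over the list alone, median 0.15, camera 0.874), and in NUP98-NSD1 1 rose and 1 fell (0 and 0 over the list alone, median -0.21, camera 0.521).

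The remaining lists were not past camera at day 5. Mitosis genes had 6 of 31 higher, among them Ccnb2 (0.26) and Kif20a (0.32) (0.0997), and ATF4 genes had 7 higher and 4 lower of 21, with Sesn2 at 0.77 and Aldh18a1 at -0.71 (0.405). MHC class II genes had 4 higher and 1 lower of 9 (5 and 1 over the list alone, 0.159), and the antigen presentation genes H2-Aa (1.99) and H2-Eb1 (2.08) rose in the mean. The H2-Aa effect differed between the fusions (F-test adjusted p = 0.000646), with -1.13 in NUP98-DDX10, 3.53 in NUP98-JARID1A and 3.56 in NUP98-NSD1. Dendritic cell genes had 2 higher, with Batf3 at 2.25, and 4 lower, with Siglech at -1.77 and Flt3 at -0.82, of 12 (0.81). The fall of Flt3 was -2.82 in NUP98-JARID1A, -0.06 in NUP98-DDX10 and 0.43 in NUP98-NSD1, and in the mean without NUP98-JARID1A the change was 0.19 (adjusted p = 0.664). Erythroid genes had 6 of 13 higher (0.159), B cell genes 0 of 13 past limma's test (1 at an unadjusted p under 0.05, 0 by edgeR and by DESeq2, camera 0.818), T and NK cell genes 5 of 16 lower (3 over the list alone, 0.293) and basophil genes 1 higher and 4 lower of 15 (0.265). Megakaryocyte genes had 1 higher and 1 lower of 9 (0.81), endothelial genes 2 and 2 of 7 (0.867, median 0.28 and mean -0.08; Cxcl12 lost its call in 16 of 21 fits without 1 library, 0.0521 to 0.101), and the fusion part genes 1 lower of 4 (0.605). At day 5 5833 genes (46%) passed the test, 2865 higher and 2968 lower, and 584 rose and 532 fell at least 2-fold.

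**Figure D3:**
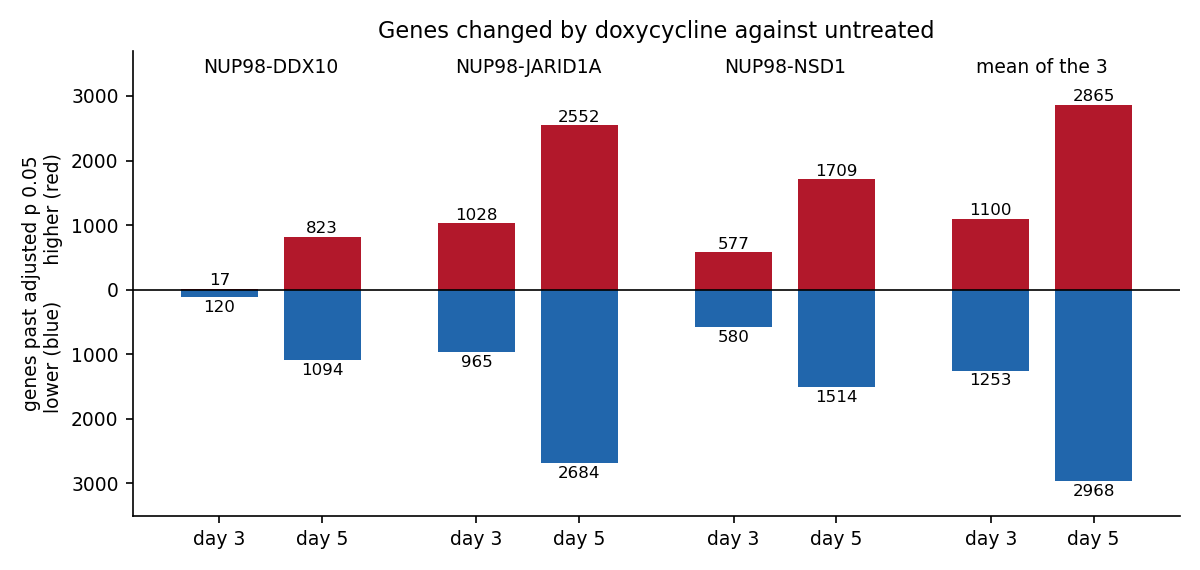
Number of genes with limma adjusted p under 0.05 in each comparison, with higher genes in red and lower genes in blue, on a linear axis from 0. Each fusion had more genes past the test at day 5 than at day 3, for example 1917 against 137 in NUP98-DDX10.

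**Figure D4:**
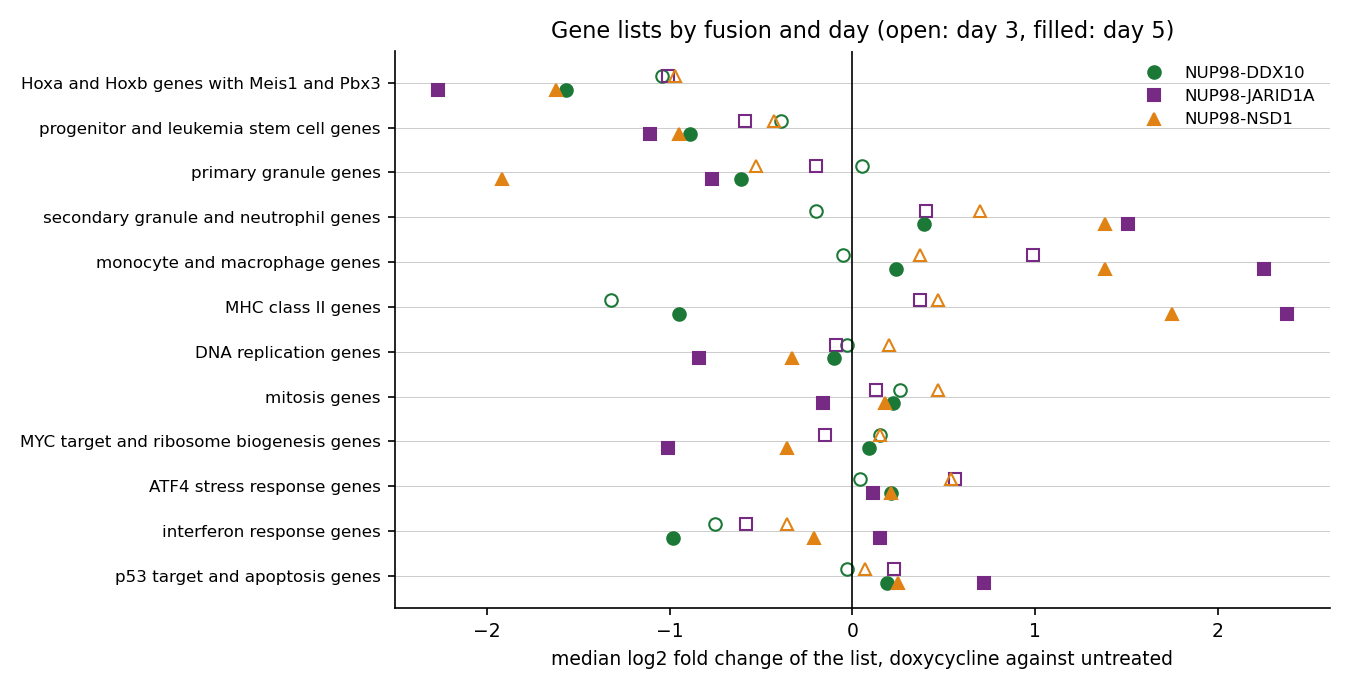
Median log2 fold change of 12 gene lists in each fusion, with day 3 as open and day 5 as filled symbols. The Hox list and the progenitor list lie below 0 and the monocyte and macrophage list lies above 0 at day 5 in each fusion.

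Between day 3 and day 5 the direct contrast of the doxycycline libraries was tested in the mean of the fusions. It found lower DNA replication and MYC target and ribosome biogenesis genes and higher monocyte genes at day 5. In NUP98-DDX10 the list medians against untreated moved little, from -0.03 to -0.1 for DNA replication and from 0.15 to 0.09 for MYC target genes. In NUP98-JARID1A the medians went from -0.09 to -0.84 and from -0.15 to -1.01. In NUP98-NSD1 they turned from 0.2 to -0.33 and from 0.15 to -0.36. Both lists were higher there at day 3 by camera (adjusted p = 3.06e-05 and 0.0485, but 0.344 and 0.724 with an estimated correlation). The MHC class II genes H2-Eb1 (2.40 ± 0.43, adjusted p = 0.000147), H2-Aa (2.36 ± 0.42) and Cd74 (1.71) rose, as did Fpr1 (1.94), Zfp36l1 (1.93 ± 0.23, 5.83e-07), C1qb (1.92), Fn1 (1.89) and Csta2 (1.83). Muc13 fell further by 2.77 (SE 0.37, 3.61e-06), Gpr171 by 1.79 (SE 0.20, 3.81e-07), Cnn3 by 1.68, Kit by 1.51 (2.48e-05), Cd34 by 1.44 and Tns1 by 1.38. Mpo, Elane and Ctsg, which encode the enzymes of primary granules, fell by 1.66 (3.37e-05), 1.38 (9.29e-05) and 1.24 (0.000108). Myc fell by 0.95 (SE 0.08, 9.32e-09), Cdk6 by 0.94 (SE 0.15, 2.55e-05), Cdk4 by 0.63 and Hoxa10 by 1.04 (3.9e-07). Of 12682 genes 3511 (27.7%) passed the test, 1817 higher and 1694 lower, but more were lower than higher under TMM scaling (1621 higher and 1881 lower) and quantile normalization (1349 and 1856). In the mean without NUP98-JARID1A 1383 passed.

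Of 38 DNA replication genes 36 fell and 1 rose from day 3 to day 5 (37 and 1 adjusted over the list alone), with Mcm5 at -0.55 ± 0.05 (adjusted p = 3.5e-08) and Mcm7 at -0.56, and camera gave 9.65e-25 (0.015 with an estimated correlation). MYC target genes had 23 of 30 lower (27 over the list alone), with Srm at -0.84 (4.69e-08) and Apex1 at -0.70 (5.86e-16, 0.0313 with an estimated correlation). Monocyte and macrophage genes had 21 of 27 higher (22 over the list alone), with Fcgr1 at 1.48 and Adgre1 at 0.65 (1.13e-09, 0.0313 with an estimated correlation). Secondary granule and mature neutrophil genes had 17 of 35 higher (25 over the list alone), with Itgam at 0.93 (1.95e-06, 0.471 with an estimated correlation). Primary granule genes had 7 of 10 lower (1.95e-06, 0.113 with an estimated correlation), and progenitor genes 13 of 27 lower (15 over the list alone, 1.95e-06, 0.0539 with an estimated correlation). The Hox list had 9 of 17 lower (10 over the list alone, 7.72e-05, 0.0678 with an estimated correlation), and mitosis genes 16 of 31 lower (18 over the list alone, 5.41e-06, 0.314 with an estimated correlation), with Cdk1 at -0.39 (6.57e-05) and Aurkb at -0.30. ATF4 genes had 10 of 21 lower and 1 higher (13 and 1 over the list alone, 0.000119, 0.0797 with an estimated correlation), with the serine synthesis gene Phgdh at -1.03 (4.73e-06) and Shmt2 at -0.71. Immediate early genes had 12 of 22 higher and 1 lower (14 and 1 over the list alone, 0.000298, 0.222 with an estimated correlation), with Jun at 1.14 and Zfp36 at 0.97. The p53 list had 7 of 21 higher and 2 lower, with Trp53inp1 at 0.98 (0.00792, 0.087 with an estimated correlation), the MHC class II list 4 of 9 higher (0.0238, 0.534 with an estimated correlation) and the interferon list 3 of 31 higher (2 over the list alone, 0.0417, 0.813 with an estimated correlation). The G1 list, with 4 of 18 higher and 7 lower (4 and 8 over the list alone), was not past camera (0.172). Nor were the lists of fusion parts and of dendritic, erythroid, B, T and NK, basophil, megakaryocyte and endothelial genes, with camera adjusted p from 0.233 to 0.824. Some calls of list members between the days were lost when 1 library was left out. Ifit3 of the interferon list lost its call in 12 of 18 such fits (adjusted p 0.0573 to 0.108) and Retnlg of the neutrophil list in 10 (0.0553 to 0.098).

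In NUP98-DDX10 at day 3 Hoxa10 fell by 1.78 (adjusted p = 1.49e-06) and Meis1 by 2.31 (0.00627, from 1823 ± 305 to 363 ± 37.2 normalized counts), and Sox4 fell by 2.17 (0.0097). Interferon response genes had 3 of 31 lower over all genes and 19 lower adjusted over the list alone (camera adjusted p = 1.62e-13, 0.368 with an estimated correlation). ATF4 genes had 0 of 21 past limma's test, also over the list alone (2 at an unadjusted p under 0.05, 0 by edgeR and by DESeq2, median 0.04, camera 0.313). In all 137 genes passed, 17 higher and 120 lower. The number rested on single libraries: it was 46, 51, 73, 69 and 77 without day 3 replicates 1 and 3, the untreated day 3 library, and untreated day 5 replicates 1 and 2. It also changed with the model, with 585 genes (171 higher and 414 lower) in a fit of the compared groups only, 1530 (623 and 907) with sample weights, 234 (43 and 191) by DESeq2 and 30 with a replicate block.

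At day 5 in NUP98-DDX10 Vcan rose by 4.23 (adjusted p = 2.43e-05, from 174 ± 90.7 to 3065 ± 670 normalized counts), Fpr2 by 3.12 and Chil3, a chitinase-like gene of myeloid cells, by 3.03. Muc13 fell by 4.68, Meis1 fell by 3.37 and Cd28 fell by 3.20. The granule protein gene Ltf, which rose in the mean, had -0.02. Progenitor genes had 12 of 27 lower (14 over the list alone, 6.88e-09, 0.0453 with an estimated correlation), the Hox list 9 of 17 lower and 1 higher (3.08e-05, 0.103 with an estimated correlation) and interferon genes 21 of 31 lower (23 over the list alone, 9.46e-11, 0.444 with an estimated correlation). Monocyte and macrophage genes had 6 of 27 higher (9 higher and 1 lower over the list alone) and were not past camera (0.0668). Nor were DNA replication genes, with 3 of 38 lower (0.0707), or MYC target and ribosome biogenesis genes, with 2 of 30 lower (1 over the list alone, median 0.09, 0.853). Of 1917 genes past the test (15.1%) 823 were higher and 1094 lower, with 1243 without day 5 replicate 2, 991 without day 5 replicate 3 and 1271 without the untreated day 3 library.

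In NUP98-JARID1A at day 3 Vcan rose by 3.79 (adjusted p = 7.5e-05), Fn1 by 2.98 and Sh3pxd2b by 2.79. Tsc22d1 fell by 2.67 (2.99e-09), the immediate early gene Fosb fell by 2.44 and Sox4 fell by 3.85. Monocyte and macrophage genes had 17 of 27 higher (20 over the list alone, camera 5.27e-10, 0.0337 with an estimated correlation), and ATF4 genes 12 of 21 higher (16 over the list alone, 5.35e-09, 0.0217 with an estimated correlation). Of 1993 genes past the test (15.7%) 1028 were higher and 965 lower, with 1246 without day 3 replicate 1.

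At day 5 in NUP98-JARID1A Fn1 rose by 6.34 (adjusted p = 5.81e-08), C1qb by 5.56 and Vcan by 4.84, and Apoe rose by 3.65 (6.4e-11). Cnn3 fell by 4.59 (5.08e-10), Muc13 fell by 4.31 and Sox4 fell by 5.95. The transcription factor genes Foxf1 and Nkx2-3 had 2544 ± 302 and 1040 normalized counts untreated and 32.2 and 32.4 at day 5. All 30 MYC target and ribosome biogenesis genes fell (camera 6.45e-15, 0.0212 with an estimated correlation), as did 34 of 38 DNA replication genes with 1 higher (35 and 1 over the list alone, 5.88e-16, 0.0212 with an estimated correlation). Monocyte and macrophage genes had 24 of 27 higher (2.72e-15, 0.0106 with an estimated correlation), p53 target genes 14 higher and 2 lower of 21 (0.000351, 0.0212 with an estimated correlation) and secondary granule and mature neutrophil genes 22 of 35 higher (26 over the list alone, 5.4e-06, 0.756 with an estimated correlation). The 5236 genes past the test (41.3%) were 2552 higher and 2684 lower, with 3658 in a fit of the compared groups only.

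In NUP98-NSD1 at day 3 the phospholipid transfer gene Pltp rose by 2.86, Plbd1 by 2.66 and Tarm1 by 2.52. Muc13 fell by 4.57, the T cell factor gene Tcf7 fell by 4.52 (adjusted p = 4.59e-06) and the cytokine gene Tnf fell by 2.56 (7.12e-07). Mitosis genes had 19 of 31 higher (25 over the list alone, camera 3.22e-17, 0.0715 with an estimated correlation). Erythroid genes had 4 of 13 higher (5 over the list alone, median 1.64, 0.000673, 0.407 with an estimated correlation). The 1157 genes past the test (9.12%) were 577 higher and 580 lower, and the number was 622, 643 and 673 without day 3 replicates 1, 2 and 3 and 768 and 771 without untreated day 5 replicates 2 and 3.

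At day 5 in NUP98-NSD1 Pltp had risen by 5.95 (adjusted p = 9.64e-11), Tarm1 by 3.91 and H2-Eb1 by 3.81. Muc13 fell by 8.73 (1.88e-11, from 4544 ± 479 to 9.94 ± 2.96 normalized counts), Tcf7 fell by 8.44 (1.15e-11, from 5988 ± 1078 to 16.8) and Chdh fell by 3.99. Primary granule genes had 9 of 10 lower (10 over the list alone, camera 4.64e-09, 0.0742 with an estimated correlation), with Mpo at -3.02 (4.4e-06). MHC class II genes had 7 of 9 higher (8 over the list alone, 0.000178, 0.297 with an estimated correlation), and monocyte and macrophage genes 20 higher and 1 lower of 27 (22 and 1 over the list alone, 4.64e-09, 0.0446 with an estimated correlation). Lists of other cell types were higher too, with erythroid genes at 4 of 13 (median 1.53, 0.0127, 0.491 with an estimated correlation), B cell genes at 2 of 13 (4 over the list alone, median 1.06, 0.0335, 0.491 with an estimated correlation) and dendritic cell genes at 4 of 12 (0.00641, 0.297 with an estimated correlation). The 3223 genes past the test (25.4%) were 1709 higher and 1514 lower, a balance that turned under TMM scaling (1533 and 1731) and quantile normalization (1483 and 1659).

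Genes past the test in the same direction in each of the 3 fusions numbered 35 at day 3, 3 higher and 32 lower, where independent calls would give 0.0627 and 0.418. Hoxa10 and Meis1 were among the 32. At day 5 there were 613, 276 higher and 337 lower, against 22.3 and 27.6, and these held Cdk6, Kit, Myc, Sox4 and Vcan. The fusions share no library in these comparisons, but they share 1 estimate of each gene's spread. The calls are therefore not fully independent, and the numbers for independent calls may be too low. The day 3 number was 14, 19, 21, 22 and 23 without NUP98-DDX10 day 3 replicate 1, day 3 replicate 3, the untreated day 3 library, untreated day 5 replicate 1 and NUP98-NSD1 day 3 replicate 1, and the day 5 number was 403 without NUP98-DDX10 day 5 replicate 3.

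The effect of doxycycline differed between the fusions for single genes, in size or in direction. Bbx, an HMG-box gene, fell in NUP98-JARID1A from 3805 to 1174 and 976 normalized counts, but was 585, 680 and 667 in NUP98-DDX10 and 496, 544 and 742 in NUP98-NSD1 (F-test adjusted p = 3.85e-08 at day 3 and 6.13e-11 at day 5). The integrin gene Itgb5 rose by 1.97 in NUP98-JARID1A at day 5, with -1.18 in NUP98-DDX10 and -1.23 in NUP98-NSD1 (4.04e-12). The kinase gene Camk1d had 3.15 in NUP98-NSD1, 1.71 in NUP98-JARID1A and -0.10 in NUP98-DDX10 at day 5 (2.68e-11). Tsc22d1 had -2.26 in NUP98-DDX10, -2.96 in NUP98-JARID1A and 0.31 in NUP98-NSD1 (3.92e-08), and Slc43a3 had -0.55, 2.21 and -0.75 (3.54e-08). Tnf went from 2175 to 367 and 396 in NUP98-NSD1 and differed at day 3 (2.04e-05). By the F-test 894 genes differed at day 3 and 3290 at day 5.

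The untreated leukemias of the 3 fusions also differed from each other. The endothelial receptor gene Eng had 19110 normalized counts in NUP98-NSD1, 1881 in NUP98-JARID1A and 368 in NUP98-DDX10 (F-test adjusted p = 6.84e-17). Slc43a3 had 1997, 55.5 and 1789 in NUP98-DDX10, NUP98-JARID1A and NUP98-NSD1 (2.35e-19), Osbpl3 1282, 144 and 2413 (2.88e-23), Scmh1 1305, 18.4 and 781 (3.73e-20), and the Hox cofactor gene Pbx3 479, 1726 and 87.9 (2.63e-18). The apelin receptor gene Aplnr was at 2080 in NUP98-JARID1A against 42.1 and 75.6 in NUP98-DDX10 and NUP98-NSD1 (7.16e-17), and Atxn1 at 1859 against 104 and 66.7 (8.11e-17). Cdk6 did not differ past the test (0.0918). In all 8848 genes differed between the untreated fusions.

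Against the libraries titled as controls, the untreated leukemias had higher Hox and Cdk6 transcripts. Hoxa10 was 8.20 ± 0.16 higher (adjusted p = 1.07e-24), with 971, 827 and 864 normalized counts in NUP98-DDX10, NUP98-JARID1A and NUP98-NSD1 and 2.09 ± 0.82 in the controls (SD, n = 3). Hoxa9 was 7.47 ± 0.49 higher (1.66e-13), with 1581, 1552 and 1314 against 16.1 ± 16.0, and Cdk6 2.69 ± 0.20 higher (2.63e-12). Igf2bp3, an RNA-binding protein gene of fetal progenitors, was 6.47 ± 0.09 higher (5.52e-29), Mira 5.93 (3.55e-16), Hoxa7 5.27, Cd34 5.23 ± 0.64 (4.51e-08), Slc4a8 5.68 and Csta2 5.52. The neutrophil protein genes Camp (-4.31, 9.37e-11), Il1b (-5.87) and Fpr2 (-4.73) were lower, as were the antigen presentation genes H2-Eb1 (-7.44) and H2-Aa (-7.08). Many transcripts of lymphoid and erythroid cells were present in the controls and far lower in the leukemias. The B cell gene Ms4a1 had 5871 ± 4746 normalized counts in the controls and 6 reads in the 12 untreated libraries together, and the immunoglobulin joining gene Jchain 68120 ± 81680 and 78 reads. The erythroid gene Slc4a1 had 18610 ± 24820 (3430 to 47250 over the 3 libraries) and 131 reads, the T cell gene Cd3e 623.5 ± 386 and 4 reads, and the mast cell protease gene Prss34 2256 ± 1229 and 1 read. Other members were not near 0 in the leukemias, with untreated means of 1622 for Cd79b (18900 ± 20770 in the controls, from 6261 to 42870) and 287 for Klrb1c (481 ± 245). Of the basophil, mast cell and eosinophil list Il6ra had 3929 (2097 in the controls) and Siglecf 570.5 (267.3), which were higher in the leukemias. The labels do not say which cells the controls are, so the leukemia fusion and any difference in cell type vary together here.

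Of 12682 genes 8970 (70.7%) differed between the untreated fusions and the controls in the mean, 4031 higher and 4939 lower. By fusion these were 8684 in NUP98-DDX10, 8803 in NUP98-JARID1A and 8196 in NUP98-NSD1. The median of all genes was -0.095 with the deposited scaling and 0.164 after quantile normalization, which gave 5475 higher and 3874 lower. Erythroid genes (13 of 13 lower, camera 7.97e-08, 0.133 with an estimated correlation), B cell genes (13 of 13, 7.97e-08, 0.0784 with an estimated correlation), T and NK cell genes (16 of 16, 1.04e-10, 0.00526 with an estimated correlation) and basophil, mast cell and eosinophil genes (13 lower and 2 higher of 15, 3.64e-07, 0.0297 with an estimated correlation) were lower in the leukemias. Megakaryocyte genes (9 of 9 lower, with Itga2b at -5.93, 0.00345, 0.0312 with an estimated correlation), dendritic cell genes (10 of 12 lower and 1 higher, 0.0424, 0.474 with an estimated correlation), MHC class II genes (7 of 9 lower, 0.00721, 0.486 with an estimated correlation) and endothelial genes (5 of 7 lower, with Cdh5 at -3.01, 0.0439, 0.155 with an estimated correlation) followed. Secondary granule and mature neutrophil genes had 28 of 35 lower (29 over the list alone, 1.63e-05, 0.507 with an estimated correlation), interferon genes 25 lower and 1 higher of 31 (26 and 1 over the list alone, 0.0013, 0.551 with an estimated correlation), with Rsad2 at -4.79, and immediate early genes 12 lower and 1 higher of 22, with Egr1 at -4.46 (0.038, 0.507 with an estimated correlation). Higher in the leukemias were the Hox list (15 higher and 1 lower of 17, 4e-07, 0.0297 with an estimated correlation), DNA replication genes (32 and 2 of 38, with Mcm5 at 1.12, 1.14e-07, 0.154 with an estimated correlation), MYC target genes (22 and 4 of 30, with Srm at 2.16, 2.65e-05, 0.259 with an estimated correlation) and primary granule genes (7 and 2 of 10, with Prtn3 at 3.25, 0.0416, 0.507 with an estimated correlation).

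Lists without a camera call against the controls held genes that went both ways. G1 genes had 9 higher and 4 lower of 18 (0.183), with Cdk4 at 1.68, Rb1 at -1.33 and Cdkn1b at -1.26. Progenitor genes had 13 higher and 8 lower of 27 (0.306, median 0.42 and mean -0.06), and mitosis genes 12 and 6 of 31 (11 and 6 over the list alone, 0.23), with Bub1b at 0.97 and Mki67 at -0.86. Monocyte and macrophage genes had 8 higher, among them Adgre1 (1.42), and 12 lower, among them Apoe (-4.23), of 27 (0.632). ATF4 genes had 7 and 10 of 21 (0.944), with Psat1 at 1.52 and Asns at -3.14, p53 target genes 8 and 9 of 21 (8 and 10 over the list alone, 0.648), with Trp53inp1 at -3.16, and the fusion part genes 1 and 2 of 4 (0.545), with Kdm5a at -1.01 and Nsd1 at -0.57.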

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

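The tests of misassigned reads and of endogenous reads for the fusion transcript left in NUP98-JARID1A were chosen after the result was seen.

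About 3% of the NUP98-JARID1A fusion transcript was left after doxycycline (2.99% at day 3 and 2.65% at day 5), against 0.0896% or less in the other models. Misassigned reads between the libraries of all models are argued against by 0 reads of this fusion in the 20 libraries of the other models, although the 3 control libraries held 2, 63 and 14, so exchange within a pool of the control and NUP98-JARID1A libraries was not tested. Reads of the endogenous Nup98 and Kdm5a are argued against by eGFP, whose share left lay within 0.126 percentage points of that of the fusion. A share of untreated-like cells or reads and a low uniform expression of the fusion were not told apart by the test set for this. No gene (0) with an untreated mean of at least 1000 fell below 1% of it in every doxycycline library of a day. Of 3468 such genes only Mn1 (0.915%) and Foxf1 (1.26%) had day 5 means below the share of the fusion left. An untreated-like share of that size would keep both means above it, but these were the lowest of 3468 genes and their spread was not tested. No biological explanation was tested.

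The control libraries held transcripts of B cells, erythroid cells, T and NK cells and basophils that were far lower in the untreated leukemias. Scaling by a few abundant genes is argued against by quantile normalization, under which the medians of the 4 lists stayed at -9.06, -8.37, -7.83 and -5.85. A floor of 3 reads over the group for members at 0 reads left these medians unchanged. It applied to 0 B cell, 0 erythroid, 1 T and NK cell and 2 basophil genes, so it adds little. That the pattern rests on a single control library is argued against by 93% of the members being higher in each control than in each of the 12 untreated libraries. This does not show that the controls held these transcripts at like levels. What stays open is a mixed cell population in the controls, which the labels do not describe, and whether they passed the GFP sort is not known, with 13.9, 210.3 and 14.3 normalized counts of eGFP against 7445 or more in the untreated leukemias. Of the 57 members, 14 had an untreated mean of at least 10 normalized counts, among them Cd79b (1622, and 18900 in the controls), and 0 of the 57 are in another of the lists.

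ATF4 stress response genes were higher at day 3 of doxycycline in the mean (16 of 21 past the test). In NUP98-DDX10 limma called 0 of 21 (2 at an unadjusted p under 0.05, 0 by edgeR and by DESeq2, camera 0.313). In NUP98-NSD1 6 of 21 were higher (9 over the list alone, median 0.54, camera adjusted p = 3.22e-06, 0.0715 with an estimated correlation). Against an equal direct effect of doxycycline in every model stands a larger effect in NUP98-JARID1A than in NUP98-DDX10. Its camera p was 0.00466 with an estimated correlation, not adjusted, and 0.103 adjusted over the 22 lists. The adjusted value is not past the threshold, so an equal effect is not excluded. Scaling of the libraries is argued against by quantile normalization, under which 16 of the 16 were past the test. A drug effect that differs between models may still contribute beside loss of the fusion, since no doxycycline library without a fusion was sequenced.

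Among the untreated groups of 4 libraries, the only ones tested for this, the NUP98-JARID1A day 3 library stood apart in eGFP with 9450 normalized counts against 12320 to 12506 in the other 3. It was 1 of 39 tests (13 measures in each of 3 groups), fewer than the 1 in 20 that chance gives. Over all genes this library was also further from the other 3 than those were from each other. Its chi-square per degree of freedom was 33.7, 47.2 and 60.8, against 24.4, 25 and 14.6 among the others. Groups of 3 were not tested, and in these the third control library (chi-square per degree of freedom 369 and 385 against the other controls, 13 between those) and NUP98-JARID1A day 5 replicate 1 (92.6 and 171, and 20.8 between the other replicates) were far from the rest. NUP98-NSD1 day 5 replicate 1 was also apart, by less (49.2 and 34.6, and 15 between the other replicates).

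The effect of doxycycline differed between the fusions by F-tests for 894 genes at day 3 and 3290 at day 5. At day 3 the smallest adjusted p-values were those of Bbx (3.85e-08), Itgb5 (2.41e-06), Spata13 (3.19e-06), Tsc22d2 (3.46e-06), Sgms1 (3.7e-06), Camk1d (3.7e-06), Apobec1 (4.12e-06), Tnf (2.04e-05), Entpd5 (2.66e-05) and Top3b (3.52e-05). The changes in NUP98-DDX10, NUP98-JARID1A and NUP98-NSD1 were 0.24, -0.43 and -1.17 for Spata13, -0.04, -0.94 and 0.15 for Tsc22d2, 0.04, 1.13 and 0.59 for Sgms1, -0.34, 0.77 and -0.43 for Apobec1, 0.01, 0.76 and -0.34 for Entpd5 and -0.09, -1.03 and -0.40 for Top3b. At day 5 they were those of Itgb5 (4.04e-12), Camk1d (2.68e-11), Bbx (6.13e-11), Entpd5 (3.32e-09), Osbpl3 (5.55e-09), Apobec1 (1.65e-08), Tcf7 (2.84e-08), Slc43a3 (3.54e-08), Tsc22d1 (3.92e-08) and Cdkn2c (1.21e-07). The day 5 changes were -0.78, 0.67 and -0.97 for Osbpl3 and -0.12, -1.30 and 0.38 for Cdkn2c. Cdk6 differed at day 5 (0.0119), and 3511 genes differed between day 5 and day 3 in the mean.

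Construct features other than the 3 fusions held reads. The highest library value of NUP98-HOXA9 was 21.7, with group means of 13.5, 6.11 and 1.28 in NUP98-JARID1A, 7.10, 3.25 and 1.05 in NUP98-NSD1 and 5.00 ± 2.02, 4.29 ± 1.02 and 3.24 ± 3.87 in NUP98-DDX10 (untreated, day 3, day 5), and 0 in the controls. By its name it joins NUP98 to HOXA9, and mouse Hoxa9 had means of 1552, 580 and 183 in NUP98-JARID1A and 1581, 594 and 479 in NUP98-DDX10. The lowest luciferase value in a fusion library was 1222, against 473, 9 and 9 in the controls.

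For each count, other splits of the same libraries into groups of the same sizes were made. There were 35 per single comparison and 100 drawn for the others, the real one included. No other split reached the real count. The real split was thus 1 of 35 or 1 of 100, the smallest share possible, with no correction over the counts. This makes chance unlikely for each count but does not exclude it. Libraries were taken as exchangeable, which cannot be checked because animals and primary leukemias are not numbered. The real count and the highest of the other splits were 137 and 8 for NUP98-DDX10 at day 3 and 1917 and 497 at day 5, 1993 and 875 for NUP98-JARID1A at day 3 and 5236 and 3461 at day 5, and 1157 and 184 for NUP98-NSD1 at day 3 and 3223 and 1354 at day 5. In the mean of the fusions they were 2353 and 432 at day 3, 5833 and 4782 at day 5 and 3511 and 2509 between the days. Against the controls they were 8684 and 7202 for NUP98-DDX10, 8803 and 7612 for NUP98-JARID1A, 8196 and 6250 for NUP98-NSD1 and 8970 and 4986 in the mean. For genes past the test in each of the 3 fusions they were 35 and 0 at day 3 and 613 and 0 at day 5, for the F-tests of the effect 894 and 0 and 3290 and 400, and for the F-test of the untreated fusions 8848 and 4704. In each case 1 split, the real one, gave as many. Splits that call few genes per fusion can hardly give genes called in each of the 3, so the 0 and 0 there add little.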

How the results depend on the processing

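The mean without NUP98-JARID1A, the replicate block over its day 5 libraries and equal depth were tried only after the data were seen. The change of Cdk6 kept its direction and its side of the threshold in every alternative, from -0.72 to -0.58 at day 3 (adjusted p from 4.93e-10 to 0.0305) and from -1.70 to -1.39 at day 5 (2.38e-31 to 7.61e-07). The counts against the controls and of differences between the untreated fusions stayed within 1.5 times in every alternative.

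Sample weights raised several counts. They gave 1530 and 4805 genes for NUP98-DDX10 (137 and 1917), 3624 for NUP98-JARID1A at day 3 (1993), 4490 and 6055 for NUP98-NSD1 (1157 and 3223), 4054 and 7442 for the F-tests (894 and 3290), 312 and 1489 for genes past the test in all 3 fusions (35 and 613), 5048 for the mean at day 3 (2353) and 6511 for day 5 against day 3 (3511). The third control library got a weight of 0.05, so it hardly entered the shared spread. Fits of the compared groups only gave 585 and 3517 for NUP98-DDX10, 3518 for NUP98-NSD1 at day 3, 2580 for the F-test at day 3, 175 for all 3 fusions at day 3 and 3861 for the mean at day 3. These fits leave the other groups out of the spread. For NUP98-JARID1A they gave fewer genes, 1464 at day 3 and 3658 at day 5 (1993 and 5236). For NUP98-NSD1 at day 5 they gave 4299 (3223). NUP98-NSD1 thus had more genes past the test than NUP98-JARID1A at both days, where the main model had fewer. Which fusion has the largest count therefore depends on the shared spread.

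A replicate block gave 30 and 925 for NUP98-DDX10, 1059 for NUP98-JARID1A at day 3, 633 for NUP98-NSD1 at day 3, 333 and 1553 for the F-tests, 8 and 338 for all 3 fusions and 1461 for the mean at day 3. It spends degrees of freedom on numbers that paired few of the libraries (6 of 27 pairs correlated above 0.1). A block over the NUP98-JARID1A day 5 libraries alone, where each pair correlated above 0.1, gave 5483 genes (5236 without it), 5207 of them shared. Untreated libraries titled day 5 only, with fewer samples, gave 69 for NUP98-DDX10 at day 3, 555 for the F-test and 18 for all 3 fusions at day 3. DESeq2 gave 234 and 63 for NUP98-DDX10 and all 3 fusions at day 3, and the cause was not tested. Without NUP98-JARID1A, with 2 fusions in the mean, 1017, 3800 and 1383 genes passed at day 3, at day 5 and between the days, and Flt3 reversed to 0.19 (adjusted p = 0.664) because its fall lay in NUP98-JARID1A.

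An estimated correlation between genes left 32 of 142 list calls over all comparisons. The endothelial and stromal list reversed against the controls in NUP98-NSD1 under the stricter filter (adjusted p = 0.718), which tests fewer genes.

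Leaving out 1 library gave 46 to 108 genes for NUP98-DDX10 at day 3 and 991 to 1705 at day 5, 1246 to 1809 for NUP98-JARID1A at day 3, 622 to 910 for NUP98-NSD1 at day 3, and 14 to 37 and 403 to 659 for all 3 fusions. The lowest were without NUP98-DDX10 day 3 replicate 1, day 5 replicate 3, NUP98-JARID1A day 3 replicate 1 and NUP98-NSD1 day 3 replicate 1. Of the named genes' values without 1 library, 8299 kept their verdict, 255 fell below the threshold and 41 newly passed. TMM kept the verdict of 479 gene values and 137 of the 142 list calls, quantile normalization of 459 and 130, and no filter of 464 and 142. Under the TMM and quantile scalings no named gene or list reversed.

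Depth limits what can be seen of genes near 0, such as Mn1 in NUP98-DDX10 (3.62 normalized counts untreated).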

Other observations

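The values here are given as group means and library values, and no hypothesis beyond the comparisons of the report was tested on them.

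Some genes with high levels in 1 or 2 models lost most of their transcript after doxycycline. Mn1, a myeloid leukemia cofactor gene, went from 1032 to 103 and 9.44 normalized counts in NUP98-JARID1A and from 512 to 55.5 and 8.16 in NUP98-NSD1 (untreated, day 3, day 5), while NUP98-DDX10 had 3.62 untreated. Foxf1, a mesenchymal transcription factor gene, went from 2544 to 262 and 32.2 in NUP98-JARID1A. The natural killer receptor gene Klrb1c went from 833 to 46.2 and 9.21 in NUP98-JARID1A.

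The 3 control libraries differed from each other. The 10 most abundant genes took 18.8%, 19.8% and 9.4% of the total, and S100a9 took 4.63%, 4.92% and 0.52%. The X-inactivation transcript Xist had 140.1, 4243.4 and 4848.4 normalized counts in libraries that also had the Y-linked Ddx3y at 1098.2, 706.3 and 833.4, while no fusion library had more than 18.1 of Xist. The second control library had 210.3 normalized counts of eGFP and the others 13.9 and 14.3.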
